A study of Homo sapiens with 12 samples.

How the data were processed

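Messenger RNA levels were measured on single-colour Illumina bead arrays carrying 47323 probes, in 12 arrays of 2 human glioblastoma cell lines, DBTRG and U87. The arrays form 6 groups of 2: DBTRG untreated and with Y15, and U87 untreated, with temozolomide, with Y15 and with both. Per the labels, total RNA was converted to biotin-labelled cRNA and per the submitters' processing notes GenomeStudio was used, whose version is not given in the sources used here. The labels' extraction protocol speaks of frozen tissue although each sample is labelled as a cell line; the samples are treated here as the cell lines named. Nothing in the labels says whether the replicates of a group were separate cultures, so p-values measure the spread between these arrays, which may be technical. No slide, scan or hybridization batch was given in the sources used here.

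The deposited table of intensity values holds 1 signal per probe and array on a linear scale, not normalized between arrays and with no background subtracted as far as the values show. Per the file headers, the same deposited table gives a detection p-value for each probe, which sets its signal against the negative control beads of the array. A second table deposited by the authors holds log2 values of the same arrays with nearly equal medians in every column and with the order of probes within each array unchanged. Its normalization method is not given in the sources used here, and it served only as an alternative. Every column of it had a median of 6.82.

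The signals were processed with limma 3.58.1 in R 4.3.3. Background was corrected by normexp with the detection p-values, an offset of 16 was added, and the arrays were quantile normalized and put on the log2 scale. A fold change on this scale understates the change of dim probes, because of the offset. A probe was kept where its detection p-value was under 0.01 in at least 2 arrays, which held for 19354 probes. Gene names came from the platform annotation, which gave 30113 probes a single symbol and 8 several, and did not list 17202. The Entrez numbers of 30074 probes matched the RefSeq gene table, which changed 0 symbols, and the same table gave gene biotypes. Of the probes kept, 4101 had no single gene symbol and were left out of gene counts. For the 3061 genes with more than 1 kept probe, the probe with the highest mean over the 12 arrays was used, and 11423 genes were tested. Of 446 pairs of a named gene and a comparison, 3 had another probe that was called in the opposite direction. No genome build is named with the probe annotation, so no coordinates are given. Probes of near-identical genes, such as copies of U3, metallothioneins and histones, can share signal.

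The 6 group means were fitted to all 12 arrays with lmFit, which left 6 residual degrees of freedom, and spreads were moderated with eBayes (prior degrees of freedom 4.46). All p-values of single genes are two-sided limma values adjusted by Benjamini-Hochberg over the 11423 genes, with a threshold of 0.05. A called gene is one past that threshold. Values are log2 changes ± SE with 2 arrays per group. Where no array of a group detected a probe, the change is given as "at least N-fold": the brighter group's mean against the mean, per array of the dim group, of the higher of the probe's own value and the lowest detected value.

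The 34 gene lists were fixed before the data were examined, and 40 of their symbols were updated. The 30 lists with at least 5 measured genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. The same test with an estimated correlation, and fry, served as alternatives. The markers of microglia, endothelium, epithelium and lymphocytes had fewer than 5 measured genes each. The rule for named genes was also fixed before the data were examined. It takes the 8 largest called rises and falls of each treatment against untreated cells whose treated arrays lie outside the untreated range, the 4 members with the smallest p of each list that was called or had at least 3 called members, a set of genes chosen in advance, and the 5 largest called rises and falls of other comparisons. The genes chosen in advance were PTK2, PTK2B, CDKN1A, MDM2, MGMT, HMOX1, HSPA1A, DDIT3, MYC and GAPDH, of which MGMT and HSPA1A did not enter the test; a further gene and 1 of the lists are not reported here, although counts of called lists include that list. To keep the text short, the list members printed are the 2 with the smallest p of each list called for a treatment against untreated cells; that shortening was decided after the values had been seen, and the alternatives were run on every gene the rule names.

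The fit was tested on simulated data of 11423 genes with known changes in 67, 67 and 66 genes of log2 sizes 0.5, 1 and 2. For DBTRG with Y15 it recovered 16.4%, 86.6% and 100.0% of them, with 8 false calls (5.59% of calls). For temozolomide in U87 it recovered 23.9%, 88.1% and 100.0%, with 11 false calls (7.24%). The simulated noise was independent between genes, and the adjustment is stricter where fewer genes change. The measured arrays gave 1 call for temozolomide, so these shares can overstate what was recoverable there. Changes shared through the same untreated arrays were judged against 50 simulated data sets with no effect.

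Alternatives fixed before the data were examined changed the background correction and offset, the normalization, the detection filter, the choice of probes, the arrays fitted, the variance model, array weights, a replicate block and the thresholds, used the authors' log2 values, or left out each array in turn. A fit on the U87 arrays alone and a normalization without small structured RNAs were chosen after seeing the data.  Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision, and between 30.5% and 35.7% of probes were detected per array.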

Results

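The series measured gene expression after 24 h of treatment in DBTRG and U87, 2 established human glioblastoma cell lines. Y15 is a small-molecule inhibitor of focal adhesion kinase (FAK, encoded by PTK2), a tyrosine kinase of cell adhesion sites, and was given at 10 µM. Temozolomide (TMZ) is a DNA-alkylating drug used against glioblastoma. The sample titles give its dose as 20 µM and the series' design text as 100 µM, and the dose is therefore open. DBTRG cells were untreated or received Y15; U87 cells were untreated or received Y15, TMZ or both, with 2 arrays in each of the 6 groups. Between 14437 and 16889 of 47323 probes were detected per array. Within U87 the arrays with Y15 alone detected the fewest, 14437 and 15169, against 16431 and 15981 in untreated U87 and 16143 and 16756 with the combination. Replicates correlated across genes at Pearson's r between 0.986 (DBTRG with Y15) and 0.995 (U87 untreated). The first principal component held 74.0% of the variance.

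In DBTRG cells, Y15 raised genes of the ATF4 amino acid response, by a median of 5.29-fold, and lowered genes of cell division. HMOX1, which encodes the heme-degrading enzyme heme oxygenase 1, rose by 4.63 ± 0.12 on the log2 scale, 24.7-fold (limma adjusted p = 8.83e-09). PPP1R15A, whose product directs dephosphorylation of eIF2α, rose 23.6-fold, and the stress transcription factors ATF3 and DDIT3 (CHOP) rose 20.1-fold and 13.8-fold. The 8 largest rises also included the 5S ribosomal RNA gene RNA5S9 (4.18 ± 0.57), BEX2 (4.16 ± 0.14), the inducible chaperone HSPA6 (at least 13.7-fold) and CTH, an enzyme of cysteine synthesis (at least 10.5-fold); the latter 2 were detected in no untreated DBTRG array. The 8 largest falls were those of MIX23 (-2.81 ± 0.25, detected in 1 of 2 treated arrays), SERTAD4 (-2.18 ± 0.13), the nuclear lamin LMNB1 (-2.13 ± 0.16), the ephrin receptor EPHA3 (-2.11 ± 0.15), SH3BP1 (at least 3.11-fold), the cytokinesis protein ANLN (-2.02 ± 0.13), PRKACA (at least 3.17-fold) and TMTC4 (at least 2.80-fold). PTK2 itself gave -0.40 ± 0.12 (adjusted p = 0.0269), a call that was lost without replicate 2 of untreated DBTRG (adjusted p = 0.157), without replicate 1 of Y15 (0.113), under median centring (0.372), with array weights (0.0812) and with only the arrays compared (0.130). Its relative PTK2B did not pass the test (0.05 ± 0.21, adjusted p = 0.886). MYC gave 0.55 ± 0.14 (adjusted p = 0.0108, but 0.0532 without replicate 2 of untreated DBTRG and 0.0509 with array weights), and GAPDH gave -0.06 ± 0.11 (adjusted p = 0.693).

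Of 21 measured genes of the ATF4 amino acid response, 20 rose in DBTRG and 0 fell, with a median log2 change of 2.40 (also 20 when adjusted over the list alone), PPP1R15A and DDIT3 first. The secreted factor GDF15 (8.01-fold), GADD45A (3.15 ± 0.13), the ubiquitin ligase MDM2 (2.61 ± 0.23) and the cyclin-dependent kinase inhibitor CDKN1A (1.29 ± 0.10) rose as well. Of 24 immediate early and MAPK feedback genes, 18 rose and 1 fell (median 0.82), with the smallest p for EGR1 (3.71 ± 0.17) and KLF4 (at least 3.85-fold). All but 1 of the 8 measured metallothionein and zinc export genes, whose products bind or export metal ions, rose (7 genes, median 1.96), such as MT1X (3.02 ± 0.14) and MT1M (at least 6.84-fold). Of 23 NRF2 antioxidant targets 12 rose and 2 fell (median 0.58), with HMOX1 and AKR1B10 (1.70 ± 0.13) first. The 4 lists shifted upward (camera adjusted p = 1.47e-16, 7.09e-08, 1.71e-06 and 0.000172) and were called with an estimated correlation too, as was the G2/M list. For lists where it is not given, the count adjusted over the list alone equalled that over all genes.

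Cell-cycle genes fell together in DBTRG. Of 29 genes of G2/M and mitosis, 27 fell and 0 rose (median -1.29; camera adjusted p = 2.41e-17, and 0.00751 with an estimated correlation). The centromere histone CENPA (-1.73 ± 0.12) and cyclin A2, CCNA2 (-1.72 ± 0.12), had the smallest p. Of 24 genes of G1/S and DNA replication, 23 fell (median -0.85), including UHRF1 (-1.40 ± 0.15) and the replicative helicase subunit MCM4 (-1.10 ± 0.12); the adjusted p was 0.0800 with an estimated correlation. Of 13 genes of homologous recombination and the Fanconi pathway 9 fell, led by RAD54L (-1.36 ± 0.16) and CHEK1 (-1.22 ± 0.15), with an adjusted p of 0.159 with an estimated correlation. Of 18 cholesterol synthesis genes 8 fell (12 lower and 1 higher adjusted over the list alone), with ACAT2 at -1.34 ± 0.17 and SQLE at -0.83 ± 0.11, and an adjusted p of 0.164 with an estimated correlation. Replication-dependent histone genes went the other way: 8 of 12 rose (median 1.43), including H2BC5 (3.23 ± 0.14) and H1-2 (2.13 ± 0.16), with an adjusted p of 0.184 with an estimated correlation. Of 17 autophagy and lysosome genes 7 rose and 1 fell, (8 and 1 adjusted over the list alone), with SQSTM1 at 1.62 ± 0.10 and MAP1LC3B at 1.52 ± 0.12 (adjusted p = 0.122 with an estimated correlation). Of 18 NF-κB cytokine genes 9 rose and 2 fell, with TNFAIP3 at 2.85 ± 0.14 and RELB at least 1.75-fold (adjusted p = 0.159 with an estimated correlation, 0.0582 under median centring and 0.0608 without replicate 1 of untreated DBTRG). The FAK and focal adhesion list was not called, with 5 of 33 genes higher and 8 lower (camera adjusted p = 0.398).

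In all, 4313 of 11423 genes were called, 2213 higher and 2100 lower, and 1044 of them changed at least 2-fold. Centring each array on its median in place of quantile normalization gave 2164 higher and 1052 lower. Fitting only the arrays compared gave 2602 calls, against 2504 for Y15 in U87. Array weights gave 3080 in DBTRG and 3394 in U87, so which line had more called genes depended on the fit. The SD of the log2 differences between replicates was 0.297 in untreated DBTRG and 0.342 in DBTRG with Y15. It was 0.215 to 0.274 in the U87 groups. The main fit gave each gene 1 spread for both lines, so SE and p-values can be too small for DBTRG and too large for U87.

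**Figure D1:**
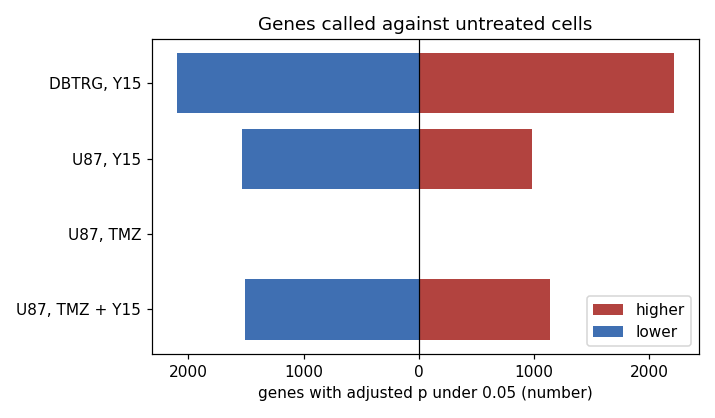
Number of genes with a limma adjusted p under 0.05 (x axis), higher to the right and lower to the left, for each treatment against untreated cells of the same line (y axis), with 2 arrays per group. DBTRG with Y15 had 2213 higher and 2100 lower genes, U87 with Y15 984 and 1532, U87 with TMZ 1 and 0, and U87 with both drugs 1137 and 1506. The difference between the lines depended on the fit: with only the arrays compared, Y15 gave 2602 calls in DBTRG and 2504 in U87.

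In U87 cells, 6 of the 8 largest rises with Y15 were those of small structured RNAs. The small nucleolar RNAs SNORD3C, SNORD3D and SNORD3A (copies of U3, which acts in ribosomal RNA processing) rose by 6.99 ± 0.61, 6.66 ± 0.63 and 6.57 ± 0.49 on the log2 scale; SNORD3C was detected in 1 of 2 untreated arrays. These near-identical copies can share signal, so they are uncertain as separate genes. RNA5S9 (5.35 ± 0.57), RN7SK, which holds the elongation factor P-TEFb inactive (5.12 ± 0.27), and RNU6ATAC of the minor spliceosome (4.36 ± 0.56, detected in 1 of 2 untreated arrays) followed. The other 2 were the transcription factor FOSB (at least 23.5-fold) and HSPA6 (19.8-fold); FOS rose at least 14.2-fold. Small RNAs that were dim in untreated cells could enter the test through arrays where they were high, which can tilt counts of them towards a rise. Over the biotypes of the gene table, DBTRG with Y15 had 25 of 101 small nucleolar RNAs higher and 5 lower, and 13 of 14 small nuclear RNAs higher and 0 lower. In U87 with Y15, 64 of 101 small nucleolar RNAs rose and 0 fell, and 13 of 14 small nuclear RNAs rose and 1, SNAR-A1 (-1.54 ± 0.28), fell. The other large falls were those of D2HGDH (-2.10 ± 0.39) and PDE5A (-1.74 ± 0.18), each detected in 1 of 2 treated arrays, VGLL3 (at least 1.84-fold), the matrix protein FBN1 (at least 2.70-fold), CHMP3 (-1.48 ± 0.21), ETV1 (at least 1.36-fold) and USP47 (at least 2.14-fold). PTK2 gave -0.52 ± 0.12 (adjusted p = 0.0139), a call lost without replicate 2 of untreated U87 (adjusted p = 0.102) or without replicate 1 (0.0560) or 2 (0.0767) of Y15. PTK2B gave 0.41 ± 0.21 (adjusted p = 0.198), MDM2 0.53 ± 0.23 (adjusted p = 0.122), HMOX1 -0.17 ± 0.12 (adjusted p = 0.363) and GAPDH 0.00 ± 0.11 (adjusted p = 0.994).

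Directions in U87 with Y15 depended on the scaling: with each array centred on its median, the median of all genes lay at -0.60. Of 21 genes of the ATF4 amino acid response, 16 rose in U87 and 0 fell (17 and 0 adjusted over the list alone; median 1.33; camera adjusted p = 5.95e-17, and 0.00735 with an estimated correlation), led by ATF3 (3.12 ± 0.17) and TRIB3 (2.82 ± 0.16), and DDIT3 rose by 2.26 ± 0.15. Of 18 NF-κB cytokine genes 12 rose and 0 fell (13 and 0 adjusted over the list alone; median 0.96; camera adjusted p = 6.85e-12), with the prostaglandin synthase PTGS2 at 2.40 ± 0.18 and the chemokine CXCL8 at 1.47 ± 0.13. GDF15 (3.49 ± 0.12), GADD45A (1.72 ± 0.13) and CDKN1A (1.08 ± 0.10) rose as well. Of 29 genes of G2/M and mitosis 23 fell and 0 rose (25 and 0 adjusted over the list alone; median -0.56; camera adjusted p = 1.01e-09), such as ASPM (-1.04 ± 0.11) and TOP2A (-1.18 ± 0.13). These 3 lists were called with an estimated correlation as well.

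The other called lists reported for this comparison were not called with an estimated correlation. G1/S and DNA replication had 11 of 24 genes lower and 1 higher (13 and 1 adjusted over the list alone; FEN1 -1.06 ± 0.11, POLA1 -0.93 ± 0.13; adjusted p = 0.280 with an estimated correlation). Replication-dependent histones had 5 of 12 higher and 1 lower (7 and 1 adjusted over the list alone; H4C14 1.56 ± 0.20, H2BC5 1.03 ± 0.14; adjusted p = 0.352 with an estimated correlation). Immediate early genes had 10 of 24 higher and 2 lower, FOS and FOSB first, with a median of 0.09, and -0.49 under median centring (adjusted p = 0.0611 with an estimated correlation). Metallothioneins and zinc export had 4 of 8 higher, with a median of 0.34, and -0.11 under median centring (MT1H 1.33 ± 0.18, MT1M 1.21 ± 0.19; adjusted p = 0.276 with an estimated correlation), and NRF2 targets 5 of 23 higher, with a median of 0.13, and -0.48 under median centring, where the call was lost at an adjusted p of 0.267 (TXNRD1 1.06 ± 0.12, SRXN1 0.86 ± 0.11; adjusted p = 0.170 with an estimated correlation). The NRF2 call was also lost without replicate 2 of untreated U87 (adjusted p = 0.0545) or replicate 1 of Y15 (0.0586). Oxidative phosphorylation had 7 of 23 lower (NDUFS1 -0.79 ± 0.17, CYC1 -0.48 ± 0.12; adjusted p = 0.296 with an estimated correlation) and hypoxia and glycolysis 7 of 21 lower (8 adjusted over the list alone; BNIP3L -0.54 ± 0.14, PGAM1 -0.58 ± 0.16; adjusted p = 0.516 with an estimated correlation, and 0.106 without replicate 2 of Y15). Each of these 4 genes lost its call with replicate 1 of Y15 left out (adjusted p = 0.0703, 0.0869, 0.0604 and 0.0747). They lost it as well in part without replicate 2 of Y15 (CYC1 0.0648, BNIP3L 0.117, PGAM1 0.106) and without untreated replicate 1 (BNIP3L 0.152, PGAM1 0.169) or 2 (NDUFS1 0.0788, CYC1 0.106). The oxidative phosphorylation call was lost under median centring (adjusted p = 0.156). The FAK and focal adhesion list had 11 of 33 lower and 1 higher (adjusted p = 0.517 with an estimated correlation, 0.0645 under median centring, 0.0834 without replicate 2 of untreated U87 and 0.106 without replicate 2 of Y15). CAV1, a membrane protein of caveolae, was among those lower (-0.80 ± 0.10), and the higher gene was the kinase gene ROCK2 (1.04 ± 0.15), of which another probe was called in the opposite direction.

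Y15 changed 2516 genes in U87, 984 higher and 1532 lower, of which 459 changed at least 2-fold. The count was 1274 without replicate 1 and 1169 without replicate 2 of untreated U87, and 1337 without replicate 1 and 1510 without replicate 2 of Y15. Under median centring 7401 genes were called, 412 higher and 6989 lower. MYC gave 0.64 ± 0.14 (adjusted p = 0.00973) after quantile normalization and -0.0274 under median centring, and its call was lost without replicate 1 of untreated U87 (adjusted p = 0.0845) or of Y15 (0.0817). Of genes named for U87 with Y15, SRXN1 (adjusted p = 0.418) and H2BC5 (0.118) also lost their call under median centring.

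**Figure D2:**
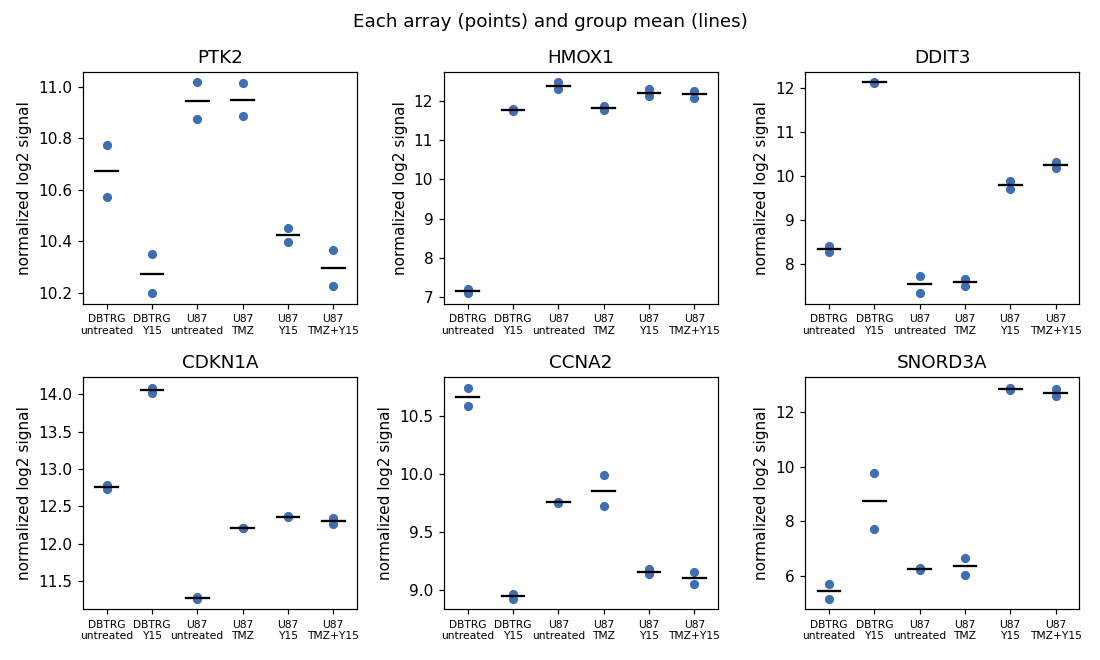
Normalized log2 signal (y axis) of 6 genes in each of the 12 arrays (points) with the mean of each group (lines), by group (x axis); the y axes differ between genes. PTK2 was lower with Y15 by a small amount, HMOX1 rose with Y15 in DBTRG by 4.63 and was already high in untreated U87, and DDIT3 rose in both lines. CDKN1A rose with each treatment, CCNA2 fell by 1.72 with Y15 in DBTRG, and SNORD3A changed with Y15 by 6.57 in U87 and 3.29 in DBTRG.

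The Y15 response was shared in part between the lines. Across the 11423 genes the log2 changes of both lines correlated at Pearson's r = 0.427 (Spearman's rank correlation 0.384), with genes not being independent replicates and no arrays shared. Of 1312 genes called in both lines, 469 were higher in both, against 190.6 expected of independent lists, 683 were lower in both, against 281.6, 125 were higher in DBTRG and lower in U87, and 35 the reverse. The test of the difference itself called 2286 genes, 1417 with a more positive change in DBTRG and 869 with a more positive change in U87. HMOX1 had the largest difference towards DBTRG (4.79 ± 0.17, adjusted p = 4.42e-07), followed by AVPI1 (3.70 ± 0.19), NDRG1 (3.52 ± 0.34), PPP1R15A (3.39 ± 0.16) and OSCAR (3.32 ± 0.26). The largest differences towards U87 were those of SNORD3C (-5.00 ± 0.86), SNORD3A (-3.28 ± 0.70), SNORD3D (-3.05 ± 0.90), RN7SK (-3.00 ± 0.38) and RIMBP3 (-2.91 ± 0.44). The difference of SNORD3D lost its call with 1 array left out in 6 of the 8 fits (adjusted p = 0.0914 and 0.0732 without replicates 1 and 2 of untreated DBTRG, 0.105 and 0.0670 without those of untreated U87, 0.0746 and 0.0895 without those of U87 with Y15), and with no filter on dim probes (0.0761) or only the arrays compared (0.0711). Of the 30 lists, 15 were called for this difference and 0 with an estimated correlation, with adjusted p from 0.0642 upward. With arrays centred on their median, the median difference of all genes lay at 0.70, against 0.0714 after quantile normalization, and 6182 genes were called, 5879 of them towards DBTRG, so the directions given are relative to quantile-normalized arrays. Without replicate 2 of untreated U87 the count was 1501.

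**Figure D3:**
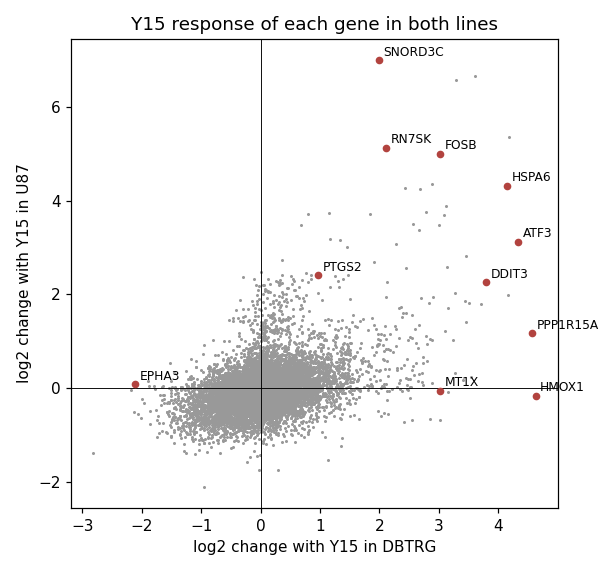
Log2 change with Y15 in DBTRG (x axis) and in U87 (y axis) of each of the 11423 genes (grey points), with 11 named genes in red. The changes correlate at r = 0.427. HMOX1 and MT1X rose in DBTRG with -0.17 and -0.05 in U87. SNORD3C and RN7SK changed by 6.99 and 5.12 in U87 and by 1.99 and 2.12 in DBTRG.

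With TMZ alone a single gene was called in U87, which does not show that other genes were unchanged. CDKN1A, the cyclin-dependent kinase inhibitor that halts the cell cycle, rose by 0.93 ± 0.10, 1.91-fold (limma adjusted p = 0.0254). An unadjusted p under 0.05 was reached by 465 genes, against 571 expected by chance. The CDKN1A call was lost without untreated replicate 1 (adjusted p = 0.434) or 2 (0.522), without TMZ replicate 1 (0.423) or 2 (0.428), under median centring (0.403), with the U87 arrays alone (0.0875) and when only the arrays compared were fitted (0.536). With a replicate block in limma the call was lost as well (adjusted p = 0.0724). Over all alternatives the adjusted p of CDKN1A ranged from 2.71e-05 to 0.536 and its log2 change from 0.87 to 0.95. PTK2 (0.00 ± 0.12), MDM2 (0.08 ± 0.23), DDIT3 (0.05 ± 0.15), MYC (-0.18 ± 0.14), PTK2B (0.04 ± 0.21), GAPDH (0.11 ± 0.11) and HMOX1 (-0.56 ± 0.12) did not pass the test. The lists of hypoxia and glycolysis (median 0.16), G1/S (0.13) and G2/M (0.10) shifted upward, and those of ribosome biogenesis (-0.12), NF-κB cytokines (-0.09) and immediate early genes (-0.14) downward, with 0 members called over all genes and 2 NF-κB genes lower when adjusted over the list alone. The members with the smallest p did not pass the test: ALDOC (0.37 ± 0.15) and, in the other direction than its list, HK2 (-0.28 ± 0.13), CCNE1 (0.41 ± 0.15) and RRM2 (0.39 ± 0.15), CCNB2 (0.36 ± 0.11) and PTTG1 (0.35 ± 0.12), RRP12 (-0.43 ± 0.13) and DKC1 (-0.30 ± 0.11), LIF (-0.58 ± 0.14) and IL1B (-0.44 ± 0.12), and IER2 (-0.42 ± 0.12) and JUN (-0.30 ± 0.11). With an estimated correlation the adjusted p of the 6 lists were 0.476, 0.641, 0.509, 0.476, 0.140 and 0.140. With 1 array left out, G2/M lost its call without untreated replicate 1 (adjusted p = 0.180) or TMZ replicate 1 (0.243), hypoxia (0.253) and ribosome biogenesis (0.102) without TMZ replicate 1, immediate early genes (0.217) without TMZ replicate 2, and NF-κB without untreated replicate 1 (0.0562) or TMZ replicate 2 (0.217). G2/M lost it under median centring as well (0.112), and none of the 6 was called by fry (adjusted p from 0.121 to 0.442).

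The combination of TMZ and Y15 gave U87 cells a profile close to that of Y15 alone. SNORD3C (6.93 ± 0.61), SNORD3D (6.56 ± 0.63), SNORD3A (6.44 ± 0.49), RNA5S9 (6.19 ± 0.57), RN7SK (4.77 ± 0.27), HSPA6 (4.63 ± 0.21), FOSB (at least 25.3-fold) and FOS (at least 16.9-fold) rose most, and 73 of 101 small nucleolar RNAs rose. The largest falls were those of D2HGDH (-1.97 ± 0.39), DEPP1 (-1.54 ± 0.18), KIAA1549L (-1.42 ± 0.14), FBN1 (-1.41 ± 0.15), LNPK (-1.40 ± 0.23), the adaptor SHC3 (-1.39 ± 0.12), TENM4 (-1.38 ± 0.16) and MIR658 (at least 1.56-fold). PTK2 was lower (-0.65 ± 0.12, adjusted p = 0.00464). CDKN1A (1.03 ± 0.10) and DDIT3 (2.71 ± 0.15) rose. MYC (0.63 ± 0.14, adjusted p = 0.0104) lost its call under median centring (0.126) and without replicate 1 of untreated U87 (0.0855) or replicate 2 of the combination (0.0645), and MIR658 without either untreated array (0.0525 and 0.0557) or that replicate (0.0603). MDM2 (0.48 ± 0.23), HMOX1 (-0.22 ± 0.12), PTK2B (0.01 ± 0.21) and GAPDH (0.10 ± 0.11) did not pass the test.

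Against untreated U87, 14 lists were called for the combination. Called with an estimated correlation too were the ATF4 response (17 of 21 higher, 1 lower; ATF3 3.61 ± 0.17, TRIB3 3.02 ± 0.16), NF-κB cytokines (12 of 18 higher, 13 adjusted over the list alone; CXCL8 1.64 ± 0.13, PTGS2 2.23 ± 0.18), NRF2 targets (7 of 23 higher, 8 adjusted over the list alone; TXNRD1 1.31 ± 0.12, SRXN1 1.15 ± 0.11) and G2/M (22 of 29 lower, 23 adjusted over the list alone; ASPM -1.23 ± 0.11, TOP2A -1.22 ± 0.13). Their camera adjusted p with an estimated correlation were 0.00829, 0.00829, 0.0405 and 0.0272. GDF15 (3.81 ± 0.12) and GADD45A (2.07 ± 0.13) rose as well.

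The other lists called for the combination were not called with an estimated correlation. The extracellular matrix list had 12 of 28 genes lower and 2 higher, with the collagen genes COL1A2 (-1.25 ± 0.15) and COL1A1 (-1.02 ± 0.15) first (adjusted p = 0.327 with an estimated correlation). The FAK and focal adhesion list had 12 of 33 lower and 1 higher, with CAV1 (-0.82 ± 0.10) and vinculin, VCL (-0.78 ± 0.12), first (adjusted p = 0.277 with an estimated correlation). Heat shock chaperones had 7 of 24 higher, HSPA6 and CRYAB (at least 1.79-fold) first (adjusted p = 0.266 with an estimated correlation). Hypoxia and glycolysis had 8 of 21 lower and 1 higher (14 and 1 adjusted over the list alone; ALDOA -0.97 ± 0.16, PFKFB4 -0.96 ± 0.19; adjusted p = 0.266 with an estimated correlation), and G1/S 14 of 24 lower and 1 higher (15 and 1 adjusted over the list alone; FEN1 -0.83 ± 0.11, POLA1 -0.91 ± 0.13; adjusted p = 0.237 with an estimated correlation). Homologous recombination had 5 of 13 lower and 1 higher (6 and 1 adjusted over the list alone; BARD1 -0.94 ± 0.15, FANCG -0.54 ± 0.11; adjusted p = 0.314 with an estimated correlation, and 0.0913 without replicate 2 of the combination; FANCG lost its call there, at 0.0574, and without replicate 2 of untreated U87, at 0.0629), histones 6 of 12 higher and 1 lower (7 and 1 adjusted over the list alone; H2AC18 1.14 ± 0.17, H2BC5 0.88 ± 0.14; adjusted p = 0.277 with an estimated correlation), metallothioneins 4 of 8 higher (MT1M 1.33 ± 0.19, SLC30A1 0.86 ± 0.13; adjusted p = 0.237 with an estimated correlation) and immediate early genes 10 of 24 higher and 3 lower, FOS and FOSB first, with a median of 0.13, and -0.0380 under median centring (adjusted p = 0.0504 with an estimated correlation). In all 2643 genes were called, 1137 higher and 1506 lower. The count was 1348 without replicate 1 and 1203 without replicate 2 of untreated U87, and 1517 without replicate 1 and 1138 without replicate 2 of the combination. Median centring, under which all genes had a median of -0.18, gave 686 higher and 1942 lower.

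**Figure D4:**
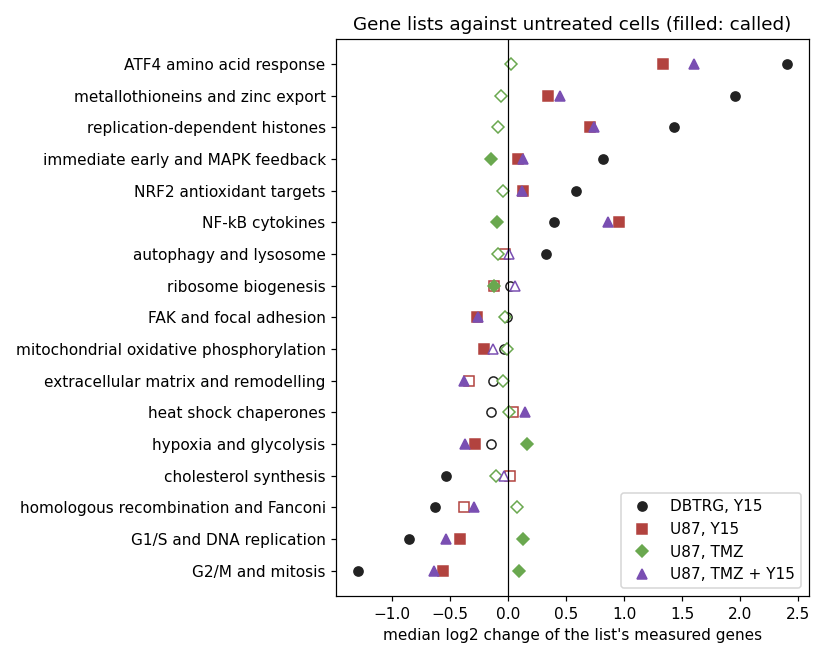
Median log2 change of the measured genes of each list (x axis) for the 17 lists reported here that were called in at least 1 treatment against untreated cells (y axis); filled symbols mark a camera adjusted p under 0.05 with the preset correlation. The ATF4 list lies at 2.40 in DBTRG with Y15 and 1.33 in U87 with Y15, and G2/M at -1.29 and -0.56.

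Adding TMZ to Y15 changed 35 genes, 10 higher and 25 lower. The largest rises were those of VPS50 (at least 1.77-fold), ZNF705G (at least 1.88-fold), RND1 (at least 1.11-fold), PM20D2 (at least 1.25-fold) and the cyclin CCNG2 (at least 1.54-fold), none detected with Y15 alone, and the largest falls those of TMEM106A (-1.40 ± 0.22), CRCP (-1.36 ± 0.22), AOC4P (-1.27 ± 0.21), DDX51 (-1.26 ± 0.13) and RAX2 (-1.25 ± 0.20). This count was unstable: it was 0 without replicate 1 of Y15 or without either array of the combination, 66 without replicate 2 of Y15, and 3715 (3640 higher, 75 lower) under median centring. The authors' values gave 149 calls (15 higher, 134 lower), and quantile normalization within each line 76 (30 higher, 46 lower). Among 7 called lists none was called with an estimated correlation. Those reported here were extracellular matrix (median -0.15), fibroblast and pericyte markers (-0.21) and FAK and focal adhesion (-0.06), lower but at 0.27, 0.17 and 0.35 under median centring, and NRF2 targets (0.12), the ATF4 response (0.20) and proteasome subunits (0.10), higher. Their adjusted p were 0.481, 0.303, 0.542, 0.303, 0.327 and 0.458 with an estimated correlation. Each of these lost its call without replicate 2 of Y15, with adjusted p from 0.0630 (extracellular matrix) to 0.217 (the ATF4 response). Of their members 1 was called over all genes, an NRF2 target.

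Adding Y15 to TMZ changed 2895 genes, 1241 higher and 1654 lower (722 and 2192 under median centring). Again SNORD3C (6.60 ± 0.61), SNORD3D (6.35 ± 0.63), SNORD3A (6.34 ± 0.49), RNA5S9 (6.20 ± 0.57) and FOSB (at least 26.6-fold) rose most, and D2HGDH (-1.90 ± 0.39), DEPP1 (-1.72 ± 0.18), ZNF395 (-1.68 ± 0.19), PRR11 (-1.52 ± 0.15) and NOMO3 (-1.52 ± 0.35, adjusted p = 0.0861 without replicate 1 of TMZ and 0.0805 without replicate 2 of the combination) fell most. The count was 1442 without replicate 1 and 1706 without replicate 2 of TMZ, and 1675 without replicate 1 and 1276 without replicate 2 of the combination. Of 15 called lists, ATF4 (16 of 21 higher), NF-κB (12 of 18 higher), immediate early genes (11 of 24 higher), G2/M (21 of 29 lower) and NRF2 (8 of 23 higher) were called with an estimated correlation. The changes with Y15 in the absence and in the presence of TMZ share no arrays; they correlated across genes at r = 0.812, and of 1705 genes called in both, 711 were higher in both (106.9 expected of independent lists) and 990 lower in both (221.8 expected). Y15 alone and the combination, both against the same untreated arrays, correlated at r = 0.871, where simulated groups without effect gave 0.5003. The covariance was 0.217 against 0.0151 in the simulation, where the untreated arrays were shared too. It was 0.207 for the changes with Y15 in the absence and presence of TMZ, which argues against shared untreated arrays as the source of most of the excess. Of 1816 genes called for both Y15 alone and the combination, 746 were higher in both (97.9 expected of independent lists) and 1069 lower in both (202.0 expected). The changes with TMZ in the absence and presence of Y15 correlated at -0.03. The test for an interaction of both drugs in limma called 0 genes, with 950 genes at an unadjusted p under 0.05, against 571 expected by chance. CCDC125 (-1.21 ± 0.16), PNLIPRP3 (1.32 ± 0.17) and DDX51 (-1.29 ± 0.18) had the smallest p (adjusted p = 0.0626 each). Other settings called between 0 and 57 genes (57 with the authors' values, 5.26% of them higher), and leaving out replicate 2 of Y15 called 17. The 5 lists called for the interaction, 0 of them with an estimated correlation, were NRF2 targets (median 0.19), ribosome biogenesis (0.24) and immediate early genes (0.18), higher, and hypoxia and glycolysis (-0.23, but 0.20 under median centring) and G2/M (-0.16, but 0.29 under median centring), lower.

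Untreated DBTRG and U87 cells differed in 6771 genes, 3060 higher and 3711 lower in DBTRG. TUBB2B (at least 167-fold), the neural transcription factor SOX3 (at least 98.8-fold), CRYAB (at least 89.1-fold), HOXB8 (at least 66.7-fold) and SERPINB5 (at least 51.5-fold) were higher in DBTRG. IL1B (at least 127-fold), IER3 (at least 87.1-fold), CYBA (at least 85.6-fold), MLPH (at least 50.2-fold) and BASP1 (-7.46 ± 0.19, detected in 1 of 2 DBTRG arrays) were lower. All 8 measured metallothionein and zinc export genes were lower in DBTRG (median -2.78), as were 12 of 18 NF-κB cytokine genes (median -1.20). Each of these lists had an adjusted p of 0.288 with an estimated correlation. The NF-κB list lost its call under median centring (adjusted p = 0.0506). HMOX1 averaged 7.15 on the log2 scale in untreated DBTRG, 11.8 in DBTRG with Y15 and 12.4 in untreated U87. Median centring gave 1495 higher and 5711 lower genes.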

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

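The tests of normalization for small structured RNAs, of near-identical copies and of a signal ceiling over all members were written before their results were seen. So was a first test of normalization for HMOX1 and metallothioneins, without all genes as a reference. Those of the lower signal of the U87 arrays with Y15, of normalization for HMOX1 and metallothioneins relative to all genes and of a ceiling for the dimmer members and for MT1X were chosen after.

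The effect of Y15 differed between DBTRG and U87 in 2286 genes by the test of the difference. Among the named genes, the difference (DBTRG minus U87, log2) was positive for HMOX1 4.79, PPP1R15A 3.39, MT1X 3.08, SNAR-A1 2.67, H2BC5 2.20, H1-2 2.20, BEX2 2.17, MDM2 2.08, PDE5A 2.03, EGR1 1.91, MT1M 1.88, TNFAIP3 1.81, VGLL3 1.71, DDIT3 1.53, CTH 1.49, GADD45A 1.43, USP47 1.41, ETV1 1.38, FBN1 1.35, CHMP3 1.31, SQSTM1 1.27, ATF3 1.21, AKR1B10 1.13, KLF4 1.03, MAP1LC3B 0.55 and CAV1 0.49. It was negative for CHEK1 -0.76, RAD54L -0.77, SQLE -0.78, ROCK2 -0.98, CENPA -1.05, ACAT2 -1.06, CXCL8 -1.10, CCNA2 -1.12, H4C14 -1.34, ANLN -1.38, PTGS2 -1.43, MIX23 -1.43, SH3BP1 -1.51, FOS -1.56, LMNB1 -1.62, TMTC4 -1.64, PRKACA -1.76, FOSB -1.97, SERTAD4 -2.15, EPHA3 -2.19, RN7SK -3.00, SNORD3D -3.05, SNORD3A -3.28 and SNORD3C -5.00. Of the gene lists, the median difference was positive for NRF2 antioxidant targets 0.21, metallothioneins and zinc export 1.44, ATF4 amino acid response 0.78, replication-dependent histones 0.82, immediate early and MAPK feedback 0.35 and autophagy and lysosome 0.33, and negative for heat shock chaperones -0.16 (0.49 under median centring), G1/S and DNA replication -0.34 (0.44 under median centring), G2/M and mitosis -0.57 (0.28 under median centring), NF-kB cytokines -0.51 (0.0321 under median centring), cholesterol synthesis -0.67 (0.0343 under median centring), homologous recombination and Fanconi -0.30 (0.54 under median centring), glioma and neural stem markers -0.48 and RNA splicing factors -0.27 (0.47 under median centring, and 0.00181 without replicate 2 of DBTRG with Y15). With 1 array left out, the calls of NRF2 targets, histones, autophagy and lysosome, heat shock chaperones, homologous recombination, glioma and neural stem markers and RNA splicing factors were each lost at least once, with adjusted p of up to 0.269 (RNA splicing factors). None of these list differences was called with an estimated correlation, and under median centring the median difference of all genes lay at 0.70. Probes without a single gene symbol, which enter no comparison of genes, were called as well: 1044 of 4101 for Y15 in DBTRG, 595 for Y15 in U87 and 652 for the combination.

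Small structured RNAs rose with Y15 in U87 and, in part, in DBTRG, where 45 of 129 tested were called higher and 5 lower (median 0.28). Of the small nucleolar RNAs, most of the set, 24.8% were called higher in DBTRG, near the 19.2% of protein-coding genes. Of the small nuclear RNAs 92.9% were. In U87 with Y15 63.4% of small nucleolar RNAs and 7.57% of protein-coding genes were called higher. The rise in U87 covered 86 of 129, with 1 called lower (median 0.93). Without any normalization between arrays the median was still 0.50, and between 0.37 and 0.66 in the 4 pairs of arrays, while all genes had a median of -0.71, which argues against normalization as the cause. In raw signal, without background correction, their median changed by 0.0299 to 0.16 in the 4 pairs. That of all genes changed by -0.62 to -0.44. Raw signal near the detection limit is mostly background and falls less in a dimmer array, so all genes are no like reference. The median raw signal of all probes, most of them not detected, was 123.4 and 118.7 in untreated U87 and 107.7 and 105.8 with Y15. The RNAs did not fall in this way, but some may have entered the test through the arrays with Y15. The test therefore cannot decide whether lower signal was part of the cause. After merging copies by name, 73 of 108 families (67.6%) had at least 1 of every 2 members called higher, so repeated copies do not account for it. A response of the cells to Y15 remains a hypothesis, and a change in how RNAs without a poly(A) tail enter the labelling was not tested.

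HMOX1 and the metallothionein list rose more with Y15 in DBTRG than in U87 (median difference 1.53 over 9 genes, of which 7 were called; adjusted p of the list 0.0842 with an estimated correlation). Without normalization between arrays the median difference of the members was 1.98 to 2.97 over 16 choices of arrays, which was the test as first written. It cannot decide the question, because all genes had median differences of 0.53 to 1.37 in the same direction. The members exceeded all genes by at least 1.23 in each choice. Subtracting the median of all genes is itself a centring of the arrays, and the choices reuse the same arrays. It shows only that the excess over all genes did not need quantile normalization, and cannot decide on scaling between arrays in general. In untreated U87 the signals reached up to 92.3% of the highest signal of the array (MT2A), with 2 of 9 members at 50% or more. The 7 other members, HMOX1 among them at 32.9%, reached at most 36.7% with Y15 in U87, which argues against a ceiling at the highest signal for these. Saturation of a single probe below the highest signal of the array was not tested. MT1X, at 56.3%, had room for 0.83 on the log2 scale but changed by -0.05 (0.23 with 2 standard errors added) and reached at most 54.1% with Y15 in U87, which argues against a ceiling at the highest signal for it too. For MT2A a signal ceiling cannot be told apart from a difference between the lines, because so bright a probe may not show a rise; it gave -0.12 in DBTRG and 0.10 in U87. The cause of the higher levels of these genes in untreated U87 was not tested, and a biological difference between the lines stays open.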

How the results depend on the processing

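The number of arrays limits every result, and leaving 1 out assumes that the lone array of its group varies like the others. The fits on the U87 arrays alone and without small structured RNAs were chosen after seeing the data. Of 6049 values of named genes under other settings, 5879 kept direction and side of the threshold, 112 fell below it, 48 passed it and 10 turned sign, all in U87 with Y15 under median centring, where the median of all genes lay at -0.60: DNAJB1 -0.17, AKR1C2 -0.0901, AKR1B10 -0.0694, SLC30A1 -0.18, TAGLN -0.24, IDI1 -0.0555, PSMD8 -0.21, ISG15 -0.15, SRSF5 -0.00638 and MYC -0.0274. With 1 array left out, 1558 of 1834 kept both and 273 fell below the threshold. Of 420 values of called lists 311 kept their call and 109 lost it.

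Median centring called 7401 genes for Y15 in U87, 0 for TMZ, 3715 for the combination against Y15, 2 for the interaction and 6182 for the line difference, with 1 list for the combination against Y15 and 2 for the interaction; r between the lines was 0.375. It takes each array's median over all probes, most of them not detected; beyond that the cause was not tested. For r, no filter on dim probes gave 0.394 and Spearman's rank correlation was 0.384. The combination against Y15 had 148 calls with normexp and an offset of 50, 135 with an offset of 50 in neqc, 76 with quantile normalization within each line, 14 with no filter and 75 with a stricter one, 134 with an intensity-dependent variance, 215 with array weights, 149 with the authors' values, 116 with the U87 arrays alone and 0 with only the arrays compared. The interaction had 37, 22, 6 and 9 calls with the normexp, offset, within-line and stricter-filter settings, 19 with an intensity-dependent variance, 12 with array weights and 57 with the authors' values. TMZ had 0 calls with every passing probe, only the arrays compared and the U87 arrays alone. DBTRG with Y15 had 2602 calls with only its own arrays. The cause of these shifts was not tested.

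At an adjusted p under 0.01 the calls were 2735 (Y15 in DBTRG), 1123 (Y15 in U87), 0 (TMZ), 1184 (combination), 4 (combination against Y15), 1326 (against TMZ) and 1027 (line difference). At 2-fold or more they were 1044, 459, 0, 434, 18, 444 and 998, and 2776 between the untreated lines. Lists called with an estimated correlation numbered 6 (Y15 in DBTRG), 4 (Y15 in U87), 1 (TMZ), 5 (combination), 0 (against Y15), 5 (against TMZ), 0 (interaction), 0 (line difference) and 0 (untreated lines). Fry, which asks whether a list's genes move on balance one way, called 20, 19, 1, 23, 4, 23 and 3 in the first 7 of these and 23 between the untreated lines.

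The replicate numbers did not pair the arrays: over 15 pairs of groups the deviations of same-numbered arrays correlated between -0.05 and 0.11. With a replicate block TMZ had 0 calls (CDKN1A adjusted p = 0.0724) and the combination against Y15 had 22. All other counts of genes and lists stayed within 1.5 times.

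With 1 array left out the calls ranged from 1169 (without replicate 2 of untreated U87) to 1510 for Y15 in U87, 0 to 0 for TMZ, 1138 to 1517 for the combination, 0 to 66 for the combination against Y15, 1276 to 1706 against TMZ, 0 to 17 for the interaction (17 without replicate 2 of Y15) and 1501 to 2355 for the line difference (1501 without replicate 2 of untreated U87). The correlation between the lines ranged from 0.377 to 0.456. Called lists ranged from 4 to 7 for TMZ, 0 to 6 for the combination against Y15 and 1 to 6 for the interaction.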

Other observations

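The test described here was chosen after the result was seen, on a hypothesis drawn from the same data. Small structured RNAs that are transcribed from promoters of their own (small nuclear RNAs, U3, 7SK, 5S and related RNAs) may have risen more with Y15 in U87 than those cut from introns of other genes. The 29 RNAs with a promoter of their own had a median log2 change of 2.74 in U87 and the 100 others 0.87. In DBTRG with Y15 the same sets had medians of 1.47 and 0.17, a contrast that was not tested. The first set includes the large rises in U87 that led to the hypothesis. With copies merged by name and the 4 families of those rises left out, 15 families with a promoter of their own had a median of 1.58 and 89 others 0.87, a difference of medians of 0.70 (two-sided permutation test over families, p = 0.00047). Families are not independent replicates, and the first set was also brighter in untreated U87, with a median of 6.296 against 5.195 on the log2 scale, so brightness was not separated from promoter type. The families kept still include small nuclear RNAs, a class of which 13 of 14 rose with Y15 in U87. The p-value therefore draws on values that lie behind the hypothesis and is no independent support for it.

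Of the markers of other cell types, listed before the data were examined, 4 lists had too few measured genes to be tested. Of the microglia and macrophage markers 4 were measured, of the epithelial markers 4, of the endothelial markers 3 and of the lymphocyte markers 2. With Y15 in DBTRG 2 of the microglia and macrophage, 1 of the endothelial, 2 of the epithelial and 2 of the lymphocyte markers rose and 0 fell. In U87 with Y15, 1 microglia and macrophage marker rose and 1 fell, 1 endothelial marker fell, 0 epithelial markers were called and 1 lymphocyte marker rose. CD68 and CD14 were picked after their values were seen: with Y15 in DBTRG they changed by 1.05 ± 0.19 and 1.49 ± 0.26 on the log2 scale (limma adjusted p = 0.00142 and 0.00128), CD14 being detected in 1 of 2 untreated arrays. In U87 with Y15, CD14 changed by 1.19 ± 0.26 (adjusted p = 0.00959), again detected in 1 of 2 untreated arrays, and CD68 gave -0.12 ± 0.19. Of the lists with enough genes, neuron markers were called lower for the combination against TMZ (3 of 8 lower, median -0.37; camera adjusted p = 0.0373, but 0.174 with an estimated correlation, 0.122 under median centring, and 0.0608 and 0.0566 without replicate 2 of TMZ and of the combination).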
